A study of Mus musculus with 6 samples.

How the data were processed

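Single-cell RNA-seq was measured in 6 mouse libraries from a series on lung organoids grown from the epithelium at the tips of the developing airway tree. The labels name 3 libraries of donor-derived cells and 3 of endogenous cells, 1 of each origin at 28, 90 and 180 dpt. The labels do not spell out dpt, which is read here as days post-transplantation. The extraction protocol in the labels describes the digestion of organoids with papain and 10x Genomics Chromium v3.1 libraries of transcript 3' ends, sequenced on a NovaSeq X Plus instrument. No sorting step for donor-derived or endogenous cells is described in the sources used here, so the gate that separated them, if any, is not known. The 28 dpt pair was registered apart from the other two pairs, so the time point and a possible processing batch cannot be told apart.

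The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 4 per the file headers and made against the mm10 genome per the submitters' processing notes. They list every barcode seen and not only called cells. Each library has the same 31054 features, 1 of which is a tdTomato reporter transcript, and 30934 of them were matched by gene identifier to GENCODE vM21. Positions are given on GRCm38, which is mm10. No gene-level normalisation was applied in the deposited counts.

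A barcode was called a cell with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 8% and removed; it marked 2.58%, 5.74% and 4.65% of the donor-derived and 2.88%, 4.28% and 3.63% of the endogenous barcodes at 28, 90 and 180 dpt. This left 57325 cells. They were normalised to their totals, reduced to 2000 variable genes and 30 principal components, joined to 20 neighbours and clustered with the Leiden algorithm (leidenalg 0.10.2) at resolution 1 and seed 1. No integration across libraries was done.

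The files give no cell annotation, so the 51 clusters were named from marker genes of 20 classes. A marker counted for a cluster when at least 20% of its cells held it at a log2 fold of at least 1 over the mean of the clusters. A cluster took the class with the largest share of its markers high, if it held at least 40 cells and at least 3 such markers. It stayed unnamed where its 10 leading genes held more markers of another class, where markers of another compartment were high too, or where few UMIs and no leading marker spoke for the name. In all, 10 clusters with 427 cells stayed unnamed. All class names are therefore "like" names.

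Cells were not treated as replicates. Raw counts were summed per library and class, and an epithelial class was tested where each library held at least 20 of its cells. Other classes were not tested gene by gene. Genes passed edgeR's filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16 quasi-likelihood tests in R 4.3.3 gave log2 changes and Benjamini-Hochberg adjusted p values, with 0.05 as the threshold. The standard error is the size of the log2 change divided by the square root of F. Origin was tested with the time point as a block, which left 2 residual degrees of freedom. Time was tested as a slope on the log2 of dpt with origin in the model, which left 3, so a log2 change over time is per doubling of dpt. That test treats the 2 libraries of a time point as independent, although only 3 time points exist. The origin by time difference is the interaction of both and left 2.

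Origin comparisons carry the block because each time point holds 1 library of each origin in the labels. The pairing was checked as the correlation, across genes and within a class, of the libraries' deviations from their origin's mean. Deviations sum to 0 within an origin, which by itself pushes the other pairings below 0, and genes are not independent replicates. For AT2-like cells the 28, 90 and 180 dpt pairs had correlations of 0.644, 0.658 and 0.750 over 5799 genes, against at most −0.171 for any other pairing of a donor-derived with an endogenous library. For AT1-like cells they were 0.731, 0.496 and 0.688 over 6622 genes, against at most 0.174.

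The tests were checked on simulated data with the real means and library sizes. With trended dispersions, 71.2% of genes changed 2-fold by origin were found in AT2-like cells and 69.4% in AT1-like cells, with 4.05% and 6.06% of calls false. Of genes with a simulated 2-fold slope, 53.0% were found in AT2-like and 63.5% in AT1-like cells, with 2.75% and 2.68% of calls false. With dispersions that varied from gene to gene, false calls were 11.6% and 1.54% for origin and 15.5% and 7.14% for time. Simulated counts for time held no shift shared by the 2 libraries of a time point, whereas the real pairs deviated together. The simulated rates therefore cannot tell how many of the real calls over time are false. The interaction test found 1.56% of 2-fold and 24.2% of 4-fold differences with trended dispersions, and 7 of its 20 calls were false with gene-wise ones. A simulated list raised 2-fold was called in each of the 4 list comparisons, and 0 of the other lists were. The simulated genes held no correlation with each other beyond the set changes. These results therefore cannot tell how many of the real list calls are false.

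The design, the 28 gene lists, the class markers, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 3 tested genes. Camera compares a list with the other genes. Its form with a correlation estimated per list and fry, which asks whether a list's own genes move one way, were alternatives. The form with an estimated correlation was not tried on the simulated lists. Whether it could call any list with 2 or 3 residual degrees of freedom is therefore not known. The list tests in AT1-like cells were added after the data were seen. The erythroid list had fewer than 3 tested genes and gave no value, as did the list of gut and gastric genes in AT1-like cells.

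The named genes are, per comparison, the 12 largest rises and the 12 largest falls among genes past the threshold with an average log2 CPM of at least 4 and the same sign at all 3 time points, or in both origins from 28 to 180 dpt for time. Predicted genes with Gm or Rik names were left out. Added to them are up to 4 members with the smallest p of each described list at that level, a fixed set of lung genes (Sftpc, Ager, Hopx, Nkx2-1, Sox9, Krt8, Scgb1a1, Foxj1 and Epcam), the reporter, Xist, Ddx3y and strain-linked genes. Where no gene passed, the 5 smallest p per direction are given as values. Foxj1 and H2-Ea-ps, and Sox9 in AT1-like cells, had too few counts to be tested.

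Free RNA was estimated from droplets of at most 100 UMIs, as the share of a class's counts that genes of other compartments need to come from that background. It uses marker genes of other compartments whose mean level in the donor-derived cells of the class was under 25% of that in the donor-derived background. The median ratio also needs a background CPM of at least 20, which left 10 to 21 genes in donor-derived and 53 to 62 in endogenous libraries. The 2 origins thus rest on different genes, and the choice by level in donor-derived cells may itself lower the donor-derived shares. Reporter shares were also taken after thinning each cell to 2000 UMIs. Intervals are exact 95% Clopper-Pearson intervals and floors are 3 counts, and both cover counting error only. Shares of cells were compared with an exact two-sided sign-flip test over the 3 time points, whose smallest possible p is 0.25.

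Total UMIs per library were 68596448, 118809698 and 99919862 for the donor-derived and 61945729, 66540008 and 59899722 for the endogenous libraries at 28, 90 and 180 dpt, all barcodes included. The alternatives chosen in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, doublet calls kept, at least 2000 UMIs, at most 10% mitochondrial UMIs, a UMI minimum per library at 1/10 of the 99th percentile of its top 3000 barcodes, Leiden resolutions 0.5 and 2, equal cell numbers, no time block, each library or time point left out, and AT2-like cells without UMIs of other types. Male cells only, reporter-positive donor cells, shallow clusters left out and background subtraction were added after the data were seen. Male cells were those with a UMI of the Y-linked genes Ddx3y, Kdm5d, Uty or Eif2s3y and none of Xist. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.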

Results

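The 6 libraries held 57325 called cells: 7129, 11412 and 8582 in the donor-derived and 9254, 11422 and 9526 in the endogenous libraries at 28, 90 and 180 dpt. Median UMIs per cell were 5645, 6969 and 7629.5 in the donor-derived and 3720, 3622 and 3889 in the endogenous libraries. Each origin and time point has 1 library, and nothing in the labels says that the libraries came from separate animals. The p values of genes and cell shares below therefore measure the spread between these libraries, which may be technical. For origin, that spread also holds any origin by time difference. Camera p values set a list's genes against other genes at a preset correlation and do not measure that spread. None of these p values says anything about animals in general.

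Donor-derived libraries were almost wholly alveolar epithelium, and endogenous libraries held mostly endothelial, lymphoid and stromal cells. Epithelial classes made up 92.2 ± 1.57% (mean ± SD, n = 3 libraries) of donor-derived cells and 6.10 ± 1.76% of endogenous cells, a difference of 86.1 points (SD 1.22). AT1-like cells, the flat gas-exchange cells, were 52.6 ± 7.09% against 2.68 ± 1.12%. AT2-like cells, which make surfactant, were 38.5 ± 5.58% against 2.54 ± 0.392%. Endothelial-like cells were 2.23 ± 0.270% of donor-derived and 29.1 ± 6.98% of endogenous cells, B and plasma-like cells 1.27 ± 0.829% and 18.6 ± 9.34%, T and NK-like cells 0.965 ± 0.228% and 16.7 ± 6.44%, and fibroblast-like cells 0.710 ± 0.236% and 11.0 ± 4.55%. Club and secretory-like cells were rare in both, at 0.715 ± 0.441% and 0.348 ± 0.199%, as were ciliated-like cells at 0.398 ± 0.231% and 0.533 ± 0.164%. Among AT1-like and AT2-like cells together, AT1-like cells were 65.2%, 52.3% and 55.5% in the donor-derived and 57.7%, 49.6% and 43.3% in the endogenous libraries at 28, 90 and 180 dpt. This difference of 7.49 points fell to 2.70 points with doublet calls kept, where 2 of 3 time points went the same way (exact sign-flip p = 0.5).

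**Figure D1:**
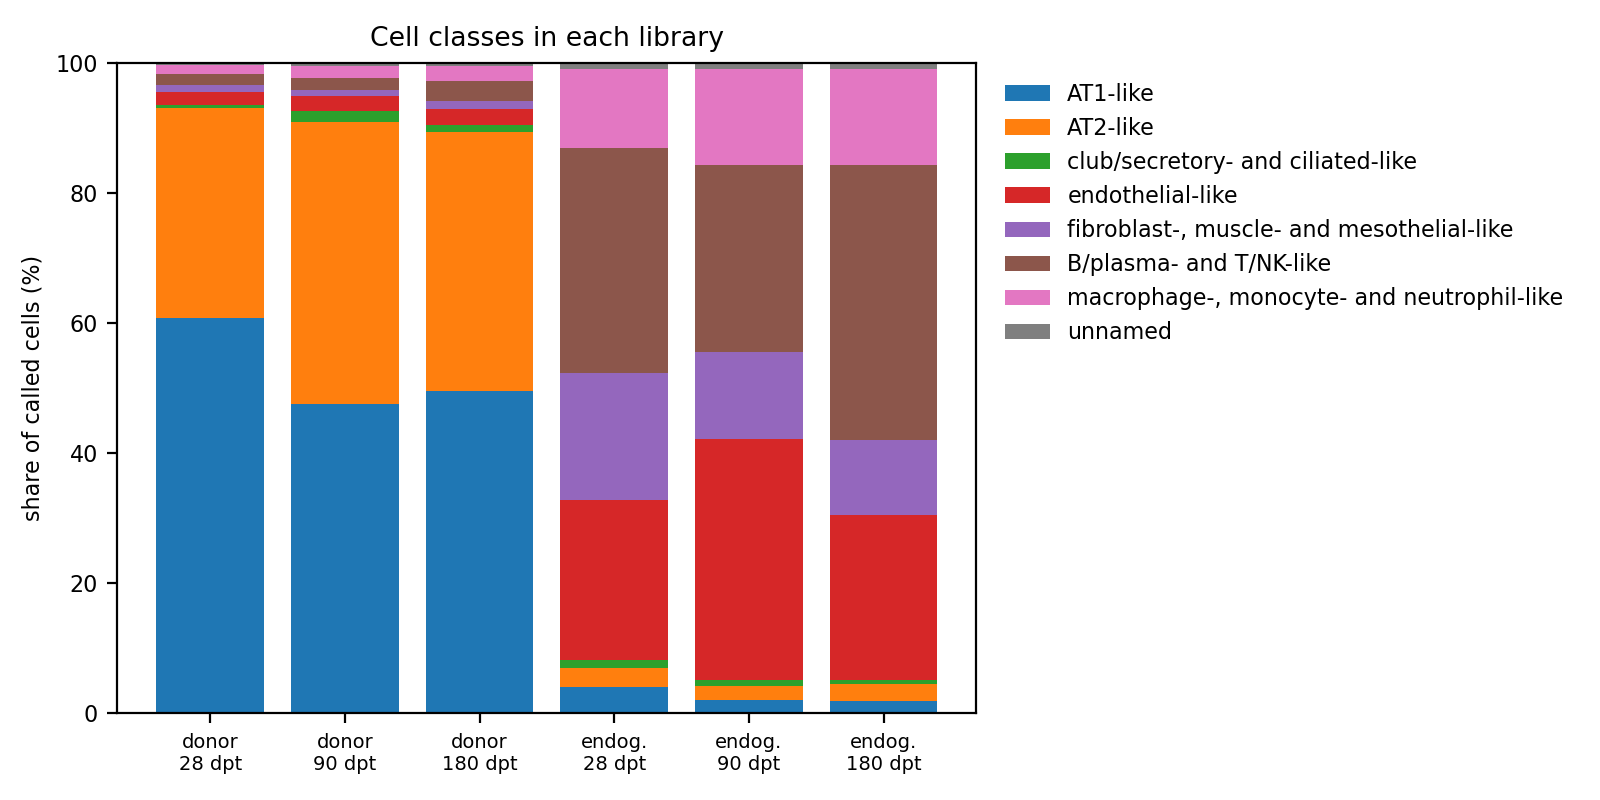
Share of called cells in each class, by library. Epithelial classes fill the donor-derived libraries, and endothelial, immune and stromal classes fill the endogenous ones.

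The exact sign-flip p over the 3 time points was 0.25, the smallest possible, for all of these shares except club and secretory-like (p = 0.5) and ciliated-like cells (p = 1). A sorting gate that the sources do not describe could set all of them, so they describe the libraries and not the lung.

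The tdTomato reporter transcript was seen in donor-derived AT2-like and AT1-like cells and in no called endogenous cell. Its level in donor-derived AT2-like cells was 63.5, 32.7 and 23.1 CPM at 28, 90 and 180 dpt, and in AT1-like cells 44.0, 24.8 and 18.5 CPM. Over all time points, 5251 UMIs in donor-derived and 0 in endogenous AT2-like cells put the donor-derived level at least 144-fold above a floor of 3 counts, and 2074 against 0 UMIs put AT1-like cells at least 44.7-fold above it. A reporter UMI was seen in 50.8% (interval 48.8 to 52.9), 31.8% (30.5 to 33.1) and 27.2% (25.7 to 28.8) of donor-derived AT2-like cells, at median depths of 13760.5, 13307.5 and 15170 UMIs. In AT1-like cells the shares were 18.0% (16.9 to 19.2), 11.3% (10.5 to 12.2) and 9.72% (8.85 to 10.7) at 4316, 4591 and 5304.5 UMIs. In non-epithelial cells of the same libraries they were 2.51% (1.26 to 4.45), 0.634% (0.206 to 1.47) and 0.777% (0.286 to 1.68) at 3819, 2839 and 3362 UMIs. Endogenous AT2-like cells had 0 of 270, 0 of 244 and 0 of 245, with exact upper limits of 1.36%, 1.5% and 1.49%. Background droplets of the donor-derived libraries held the reporter at 52.0, 39.0 and 23.3 CPM, and their non-epithelial cells at 5.24, 1.48 and 2.20 CPM. Free RNA may give the reporter UMIs of the latter, though its share was not estimated in them.

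**Figure D2:**
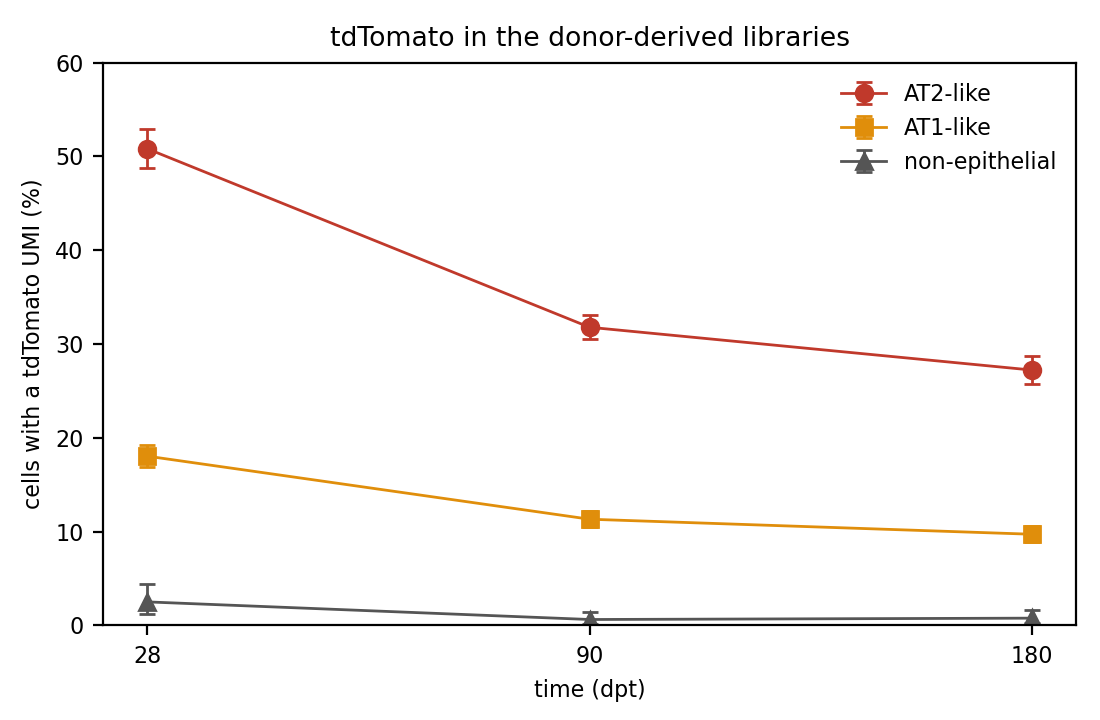
Share of cells with a tdTomato UMI in the donor-derived libraries, with exact 95% intervals, for AT2-like, AT1-like and non-epithelial cells. In AT2-like and AT1-like cells the share is lower at each later time point.

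Depth sets part of these shares. After thinning to 2000 UMIs per cell they were 12.3%, 6.36% and 4.26% in AT2-like cells (45, 137 and 48 shallower cells left out), 8.02%, 5.12% and 3.53% in AT1-like cells (488, 614 and 578 left out) and 0.824%, 0% and 0.305% in non-epithelial cells (74, 217 and 116 left out). The 0% stands for 0 of 572 cells, whose interval reaches 0.643%. These intervals cover counting error only, and cells without a reporter UMI in the donor-derived libraries cannot be assigned an origin from this transcript.

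Genes linked to sex differed by origin. Xist, the RNA that silences 1 X chromosome in female cells, was 616, 291 and 517 CPM in donor-derived AT2-like cells at 28, 90 and 180 dpt and 40.0, 2.83 and 1.91 CPM in the endogenous ones. The Y-linked helicase gene Ddx3y was lower in donor-derived AT2-like cells, at log2 −1.33 ± 0.10 (SE; adjusted p = 8.3e-06), as was the Y-linked translation factor gene Eif2s3y at −1.33 ± 0.11. In donor-derived AT2-like cells, 58.5% (56.5 to 60.5), 55.9% (54.5 to 57.3) and 56.7% (55.0 to 58.3) held Xist and no Y-linked UMI, while 27.6%, 26.5% and 29.3% held Y-linked UMIs and no Xist. In endogenous AT2-like cells, 74.1%, 84.0% and 83.7% held only Y-linked UMIs, and 5 of 270, 1 of 244 and 1 of 245 only Xist, at median depths of 14423, 15366 and 17884 UMIs. Donor-derived AT2-like cells were thus a mix of cells with female and male transcripts, and endogenous ones were mostly male. Each comparison of origin was repeated with male cells only, as described below where that changes a result.

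In AT2-like cells, 1243 of 12487 tested genes differed by origin, 354 higher and 889 lower in donor-derived cells (n = 3 libraries per origin). Sftpc, the surfactant protein C gene, was at log2 0.18 ± 0.11 (adjusted p = 0.37), and the lung regulator Nkx2-1 at 0.09 ± 0.10, neither past the threshold. The largest rises next to the reporter and Xist were in Pde1c, a calcium/calmodulin-dependent phosphodiesterase (2.28 ± 0.42, adjusted p = 0.0038), and in Dmkn, the secreted epidermal protein dermokine (2.23 ± 0.33; 203 ± 72.8 against 43.3 ± 22.7 CPM, chr7:30763756–30781063). Meg3, an imprinted noncoding RNA, rose by 2.09 ± 0.32, Kng2, a kininogen, by 2.08 ± 0.21, Tmem213 by 1.67 ± 0.15 and the cytoskeletal adaptor Sorbs2 by 1.63 ± 0.25. Phgr1 (1.52 ± 0.36), Itm2a (1.34 ± 0.17) and Pbld2 (1.27 ± 0.15) rose too. Heatr1, which acts in ribosomal RNA processing, rose by 1.34 ± 0.10 (77.1 ± 4.90 against 30.5 ± 1.12 CPM, chr13:12395027–12440289). Of the falls, Ccnd2, the cell-cycle regulator cyclin D2 (−3.15 ± 0.12, adjusted p = 2.7e-08; 4.54 ± 1.21 against 40.5 ± 11.5 CPM, chr6:127125162–127152193), had the smallest p. The lipid carrier gene Apoe fell by 2.10 ± 0.21 (80.6 ± 36.5 against 322 ± 25.8 CPM), Ifitm3, an interferon-induced membrane protein gene, by 2.08 ± 0.17, and Nrn1 by 2.07 ± 0.29. The growth factor binding protein gene Igfbp6 fell by 2.02 ± 0.13, Fmo2 by 1.71 ± 0.23, and Cavin2, a caveola coat gene, by 1.59 ± 0.18. Genes of other cell types fell too: S100a9, a neutrophil calprotectin subunit (−6.55 ± 0.59), the immunoglobulin kappa gene Igkc (−4.46 ± 0.40), the matrix Gla protein gene Mgp (−4.13 ± 0.28), and the club cell genes Scgb1a1 (−3.07 ± 0.70) and Cyp2f2 (−1.59 ± 0.35). Scgb1a1 fell unevenly and most at 28 dpt, at 64.4, 518 and 599 CPM in donor-derived against 3498, 4013 and 1205 CPM in endogenous cells.

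Of 16 surfactant and lamellar body genes, 0 rose, 1 fell and 15 did not pass (camera adjusted p = 0.465; median log2 0.09, mean −0.03). Of 18 lung transcription factors, Foxp2 (0.60 ± 0.11) and Id2 (0.34 ± 0.10) rose and 16 did not pass. Cholesterol synthesis was the only list called higher, with 2 of 19 genes rising, Fdps (0.66 ± 0.15) and Mvd (0.40 ± 0.11), and 5 when adjusted over the list alone. Its adjusted p = 0.0325 became adjusted p = 0.703 with an estimated correlation. In the list of TGF-beta, YAP and matrix genes 7 of 22 fell, among them the BMP target Id3 (−1.24 ± 0.14), the matrix protein gene Tgfbi (−0.92 ± 0.12) and the laminin gene Lamb3 (−0.42 ± 0.09). The list had adjusted p = 0.0325, and adjusted p = 0.6 with an estimated correlation. In the p53 and senescence list 5 of 16 fell and 1 rose, with 6 and 1 over the list alone (adjusted p = 0.032; adjusted p = 0.703 with an estimated correlation). Among the falls were Gdf15, a stress cytokine gene (−1.22 ± 0.17), Cdkn1a, which encodes the cell-cycle inhibitor p21 (−0.94 ± 0.14), Plk2 (−0.90 ± 0.16) and Ccng1 (−0.54 ± 0.11). Of 10 genes of MHC class II presentation, 1 fell, and 5 did over the list alone (adjusted p = 0.032; adjusted p = 0.56 with an estimated correlation). H2-Ab1 was short of the threshold at −0.33 ± 0.10 (adjusted p = 0.061). Of 18 genes of the AT1 programme 4 fell and 14 did not pass, with 5 falls and 1 rise over the list alone. Among the falls were the caveola gene Cav1 (−1.33 ± 0.18), Clic5 (−0.95 ± 0.11) and Ahnak (−0.59 ± 0.10). The list was not called (adjusted p = 0.234). In the stress list the heat shock genes Hspa1b (1.11 ± 0.16), Dnajb1 (0.93 ± 0.17) and Hspa1a (0.85 ± 0.17) rose, Ier3 fell by 0.54 ± 0.12, and 17 of 21 did not pass, with 6 rises and 3 falls over the list alone. Hspa1a and Hspa1b are near-identical in sequence, so their counts cannot be told apart with certainty. In the inflammatory list 5 of 20 rose and 4 fell, or 7 and 6 over the list alone, with Il33, an alarmin (0.77 ± 0.11), and Lcn2, lipocalin 2 (0.75 ± 0.12), among the rises.

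Markers of other cell types fell as groups: 12 of 14 macrophage and monocyte genes, and 13 over the list alone (adjusted p = 1.12e-31; adjusted p = 0.278 with an estimated correlation) and 12 of 12 lymphocyte genes (1.24e-27; adjusted p = 0.278 with an estimated correlation). So did 13 of 14 endothelial genes (1.04e-87; adjusted p = 0.278 with an estimated correlation) and 8 of 10 mesenchymal genes, and 9 over the list alone (9.36e-10; adjusted p = 0.29 with an estimated correlation). Examples were Lpl, lipoprotein lipase, at −1.51 ± 0.21, and the endothelial gene Egfl7 at −0.91 ± 0.13. Airway secretory genes fell in 5 of 9 and rose in 1, with 8 and 1 over the list alone, including the carbonyl reductase gene Cbr2 (−0.78 ± 0.11). That list had adjusted p = 0.00121, and adjusted p = 0.6 with an estimated correlation. The list of sex-linked and strain-linked genes was called lower (2 up and 4 down of 7, adjusted p = 0.00121; adjusted p = 0.347 with an estimated correlation). Its median log2 was −1.33 and its mean 0.11, as Xist rose far more than any Y-linked gene fell. By the median ratio, free RNA was estimated at 1.49%, 1.03% and 0.779% of the counts of donor-derived AT2-like cells and at 4.82%, 6.28% and 2.99% of those of the endogenous ones. By the summed ratio it was 2.47%, 2.85% and 0.792% against 4.02%, 5.96% and 2.48%. Both ratios use genes chosen for a low level in donor-derived cells, which may add to this difference. The AT2-like class was also not made of the same clusters throughout. A cluster led by Bex2, Slc34a2 and Cxcl15 held 37.3%, 27.4% and 65.4% of donor-derived cells at 28, 90 and 180 dpt. Of endogenous cells it held 32.2%, 53.7% and 76.3%. A cluster led by Scd1, Il33 and Hc held 18.7%, 51.6% and 18.6% of donor-derived and 10.7%, 18.0% and 3.67% of endogenous cells. One led by Areg, Egfl6 and Sftpd held 29.4%, 8.45% and 9.45% of donor-derived and 42.2%, 15.2% and 9.80% of endogenous cells.

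**Figure D3:**
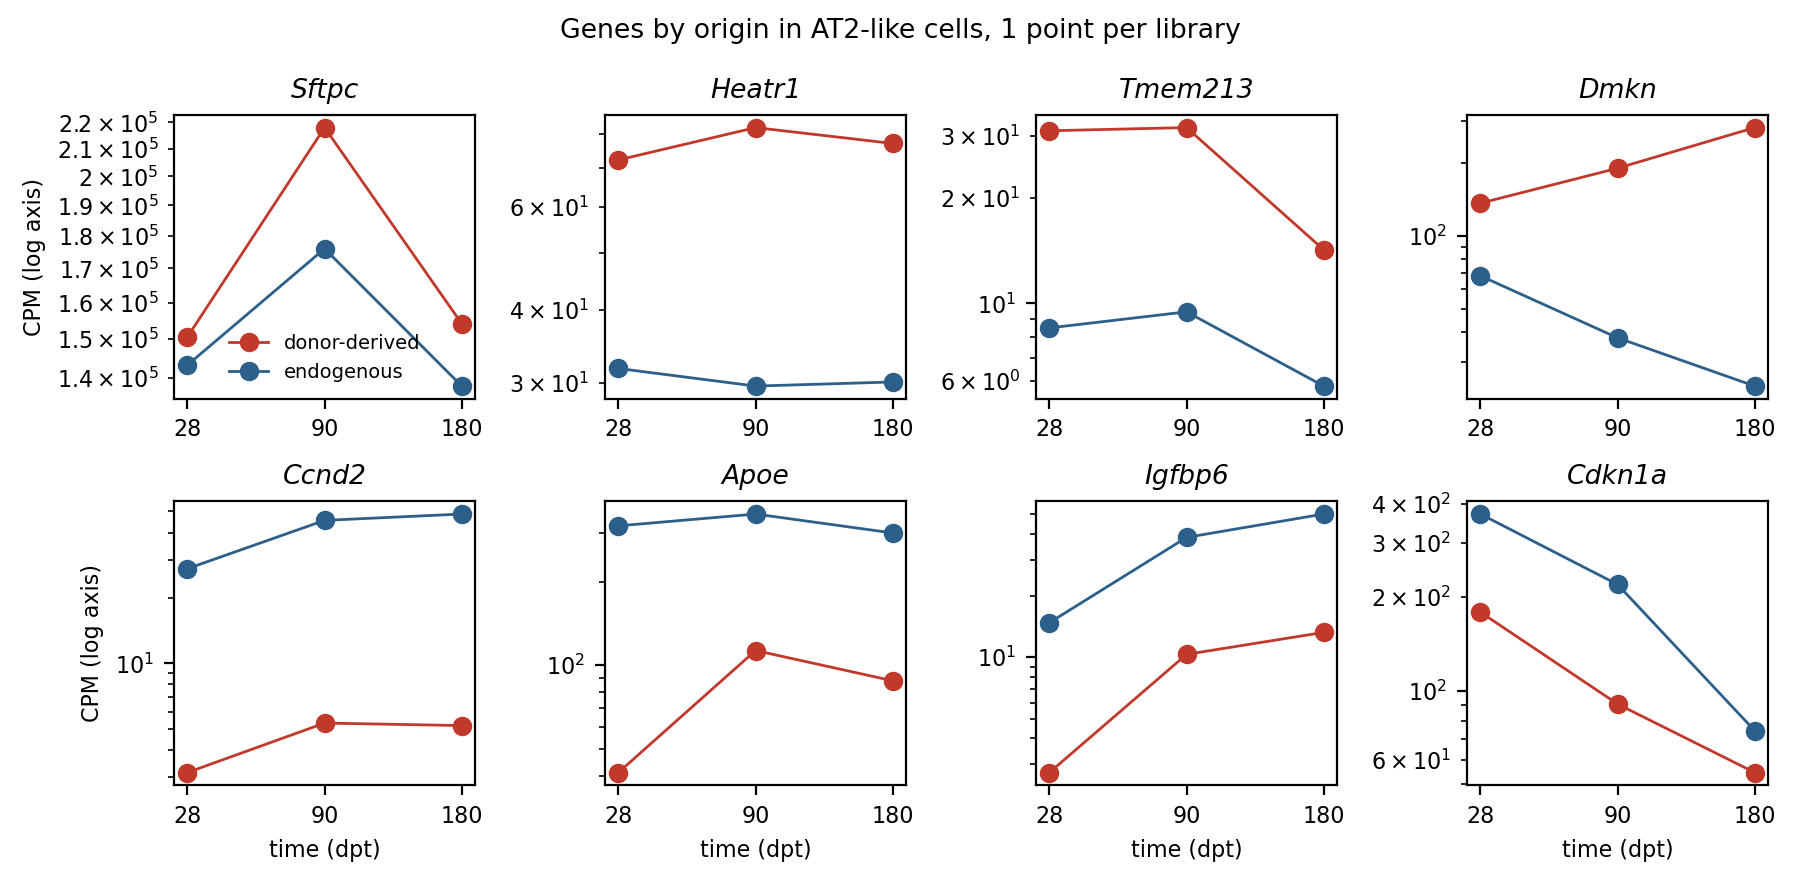
Level of 8 genes in AT2-like cells, with 1 point per library against time. Sftpc overlaps between origins, Heatr1, Tmem213 and Dmkn are higher in donor-derived cells, and Ccnd2, Apoe, Igfbp6 and Cdkn1a are lower.

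Of the other 9 splits of the 6 libraries into 3 and 3, the highest gave 0 genes, but 10 splits are too few for a share under 0.05. Most of the other splits part the libraries of only 1 time point. With the time block their contrast rests on that time point alone, so they are not like the split by origin. Without the time block 582 genes passed, 38 higher and 544 lower, and 9 of the 24 genes chosen by size lost their calls. Without the donor-derived library at 28 dpt 2103 genes passed, 1087 higher and 1016 lower, and without the endogenous one 2285, 1145 higher and 1140 lower, so the excess of falls was not kept. Counts were lower without those at 90 dpt, at 727 or 764. With male cells only 815 passed, and after background was subtracted by the median or summed ratio 437 or 507 did. All 24 genes chosen by size, the reporter and Xist included, passed with the block and without each library. With the time block, a library left alone at its time point holds no information on origin. Leaving out either library of a pair thus rests origin on the same other pairs, with fewer than 2 residual degrees of freedom. These omissions are nearly 1 check per time point and not 1 per library. Background subtraction by the median and summed ratio ended the calls of Ifitm3 (−0.14 and −0.49), Id3 (−0.38 and −0.67) and Egfl7 (−0.22 and −0.33), which shrank, and of Fmo2, which turned to 0.18 and shrank to −0.26. It also ended those of Scgb1a1 (−3.04 and −3.45), Cyp2f2 (−1.64 and −1.66), Phgr1 (1.44 and 1.45), Fdps (0.58 and 0.59), Mvd (0.33 and 0.35) and Id2 (0.29 and 0.30), whose size moved less. The call of Cavin2 (−2.49) ended in the summed form and that of Ier3 (−0.49) in the median form. Male cells only or DESeq2 ended the calls of Scgb1a1, Cyp2f2 and Mvd. Male cells only also ended those of Id2, Lamb3, Ddx3y and Eif2s3y, DESeq2 those of Phgr1 and Hspa1a, and reporter-positive donor cells those of Id2, Mvd and Phgr1. For Ddx3y and Eif2s3y that loss was set by the choice of male cells, which uses their UMIs. Among list members, Fdps (0.42 and 0.44) and Ccng1 (−0.44 and −0.42) lost their calls without the donor-derived or endogenous library at 90 dpt. Mvd (0.35 to 0.42), Id2 (0.31 to 0.37) and Lamb3 (−0.41 to −0.37) lost theirs without any 1 of the 4 libraries at 90 and 180 dpt. Ier3 (−0.50) lost its call without the endogenous one at 90 dpt, Lcn2 (0.60 and 0.62) without the donor-derived or endogenous one at 180 dpt, and Hspa1a (0.55) without the donor-derived one at 180 dpt.

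Of the list calls, cholesterol synthesis ended without the donor-derived library at 90 or 180 dpt (adjusted p = 0.0991 and 0.0887) and without the endogenous one at 90 dpt (0.0673). Without the donor-derived library at 28 dpt the TGF-beta, YAP and matrix (0.214), p53 and senescence (0.0955), MHC class II (0.178) and airway secretory (0.0634) calls ended. The TGF-beta, YAP and matrix (0.226) and p53 and senescence (0.108) calls also ended without the endogenous one at 28 dpt. MHC class II also ended without the donor-derived library at 90 dpt (0.103) and turned to higher in AT2-like cells without UMIs of other cell types (0.0167). The cholesterol synthesis (0.562), TGF-beta, YAP and matrix (0.149) and sex-linked and strain-linked (0.665) calls ended in those cells. Only 20, 7 and 7 such endogenous cells were left at 28, 90 and 180 dpt. These changes therefore cannot be told from the loss of cells. The sex-linked and strain-linked list turned to an uncalled rise without the donor-derived or endogenous library at 28 dpt (0.951 and 0.956). It ended without the donor-derived one at 90 or 180 dpt (0.0723 and 0.326) or the endogenous one at 180 dpt (0.492). The macrophage and monocyte, lymphocyte, endothelial and mesenchymal calls passed without each library.

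In AT1-like cells, the surfactant list was called higher and the TGF-beta, YAP and matrix list lower in the donor-derived libraries, though neither was with an estimated correlation. Of 11701 tested genes 1309 differed, 590 higher and 719 lower (n = 3 libraries per origin). Vsig2, an immunoglobulin-domain membrane protein gene, rose by 3.98 ± 0.21 (adjusted p = 1.6e-10; 117 ± 28.2 against 6.86 ± 2.41 CPM, chr9:37539255–37544205). The fatty acid binding protein gene Fabp5 (3.37 ± 0.40) and the surfactant protein genes Sftpa1 (3.06 ± 0.18) and Sftpb (2.24 ± 0.20) rose next. So did the AT2 chemokine gene Cxcl15 (2.80 ± 0.24), the lysozyme gene Lyz2 (2.41 ± 0.22), Chil1 (2.35 ± 0.24), the phosphate transporter gene Slc34a2 (1.63 ± 0.32) and Cdkn2c, a cyclin-dependent kinase inhibitor gene (1.60 ± 0.29). Sftpc itself rose by 1.16 ± 0.23 (2190 ± 687 against 986 ± 374 CPM), far below its level in AT2-like cells. Its gap was widest at 90 dpt, at 2016, 2921 and 1466 CPM before TMM scaling in donor-derived against 1304, 635 and 1072 CPM in endogenous cells. Xist (4.88 ± 0.29) and Tsix (2.61 ± 0.25) rose with sex, and as they overlap on opposite strands their reads may be shared. Of the falls, Mgll, monoglyceride lipase (−3.80 ± 0.17), and the membrane glycoprotein gene Gpm6a (−3.73 ± 0.17; 15.3 ± 13.2 against 181 ± 111 CPM, chr8:54954843–55060871) were the largest outside immunoglobulins. Mgp (−2.88 ± 0.14), the growth factor binding protein gene Igfbp2 (−2.80 ± 0.35), Scel, sciellin (−2.46 ± 0.21), Ccnd2 (−2.31 ± 0.13; 53.9 ± 4.06 against 274 ± 79.6 CPM), the collagen lysyl hydroxylase gene Plod2 (−2.21 ± 0.18) and the calponin gene Cnn3 (−2.04 ± 0.19) followed. Gstm2 fell by 2.47 ± 0.16, but its close paralogs may share reads. The AT1 markers Ager (0.23 ± 0.15) and Hopx (0.10 ± 0.14) did not pass, while the epithelial adhesion gene Epcam (0.84 ± 0.13) and the keratin gene Krt8 (0.36 ± 0.11) rose and Scgb1a1 fell by 1.34 ± 0.38. That fall was uneven, at 17.8, 161 and 76.7 CPM in donor-derived against 193, 150 and 166 CPM in endogenous cells at 28, 90 and 180 dpt. Igha (−9.31 ± 0.32), Jchain (−7.77 ± 0.61) and Igkc (−6.72 ± 0.73), all plasma cell transcripts, fell. In the endogenous library at 28 dpt 1 cell held 1558 of 1609, 1044 of 1090 and 5541 of 5671 of their UMIs. These are maxima per gene, which need not be the same cell. At 90 and 180 dpt Igkc still had 50 and 42 UMIs in 240 and 187 endogenous cells, of which 26 and 25 lay in 1 cell. Donor-derived cells then numbered 5421 and 4258 and held 40 and 54.

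Among gene groups, surfactant and lamellar body genes rose in 12 of 16 and fell in 1, with 13 and 1 over the list alone (median log2 1.32; camera adjusted p = 1.86e-23; adjusted p = 0.256 with an estimated correlation). In the TGF-beta, YAP and matrix list 8 of 20 fell and 2 rose, with 10 and 2 over the list alone (adjusted p = 0.00452; adjusted p = 0.622 with an estimated correlation). The YAP target Ctgf (−1.04 ± 0.17), the collagen IV gene Col4a2 (−0.56 ± 0.13) and the integrin gene Itgb6 (−0.52 ± 0.12) fell and the fibronectin gene Fn1 rose (1.24 ± 0.24). Of 18 AT1 programme genes 5 fell and 1 rose, and the list was not called (adjusted p = 0.244). The angiogenic factor gene Vegfa (−0.53 ± 0.13) and Sema3e (−0.49 ± 0.13) were lower and the water channel gene Aqp5 (0.52 ± 0.13) was higher. Of 16 transitional genes 5 rose and 2 fell, with 7 and 2 over the list alone (adjusted p = 0.0588). Clu, clusterin (0.98 ± 0.12), and Sfn, 14-3-3 sigma (0.62 ± 0.14), were higher and Cdkn1a was lower (−0.61 ± 0.11). Of 16 p53 and senescence genes 4 fell and 1 rose, or 4 and 2 over the list alone, with Ccng1 (−0.78 ± 0.11) and Phlda3 (−0.82 ± 0.18) lower. In the interferon list 5 of 26 rose and 1 fell, or 6 and 1 over the list alone, with Ifit1 (0.51 ± 0.12) and Ifit3b (0.67 ± 0.17) higher and adjusted p = 0.0549. Of 7 genes of MHC class II presentation 2 fell, and 5 over the list alone, among them H2-Eb1 (−0.93 ± 0.22), at adjusted p = 0.0559. Bex4 (1.06 ± 0.17) and Foxp2 (0.66 ± 0.13) rose, as did Scd1, a fatty acid desaturase gene (1.19 ± 0.25), Lcn2 (1.44 ± 0.31) and the lactate dehydrogenase gene Ldha (0.47 ± 0.11). Scd2 (−0.65 ± 0.14) and the chaperone gene Hspa5 (−0.47 ± 0.12) fell.

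Other cell type markers fell here too: 9 of 10 macrophage and monocyte genes (adjusted p = 3.65e-24; adjusted p = 0.217 with an estimated correlation) and 11 of 12 lymphocyte genes (4.42e-35; adjusted p = 0.247 with an estimated correlation). The same held for 11 of 12 endothelial genes (2.18e-22; adjusted p = 0.256 with an estimated correlation), 10 of 12 mesenchymal genes (3.29e-12; adjusted p = 0.256 with an estimated correlation) and 4 of 8 airway secretory genes (0.000302; adjusted p = 0.542 with an estimated correlation). The airway secretory call ended without the donor-derived library at 28 dpt (adjusted p = 0.876). Free Sftpc stood at 70193.3, 130348 and 83900.8 CPM in the donor-derived background and at 14354.5, 15941.7 and 18924.9 CPM in the endogenous one. An equal share of free RNA would thus carry more Sftpc into donor-derived AT1-like cells. By the median ratio, free RNA was estimated at 5.27%, 1.72% and 0.769% of donor-derived AT1-like counts and 3.65%, 1.21% and 1.78% of endogenous ones. By the summed ratio it was 4.15%, 3.18% and 0.824% against 30.1%, 1.77% and 2.38%. The 30.1% is not free RNA alone, since it was 4.15% without Igkc, Jchain, Ighm and Mzb1, and nearly all UMIs of Igkc and Jchain lay in 1 cell per gene, as described above. Subtraction by the summed ratio therefore likely takes too much from the endogenous AT1-like library at 28 dpt. The AT1-like class changed its make-up with time. A cluster led by Col4a3, Col4a4 and Rtkn2 held 82.4% of donor-derived and 60.1% of endogenous cells at 28 dpt. A cluster led by Ager, Cyp2b10 and Rtkn2 held 8.97%, 69.5% and 39.5% of donor-derived cells at 28, 90 and 180 dpt. Of endogenous cells it held 18.5%, 25.8% and 18.7%. A cluster led by Igfbp2, Ndnf and Vegfa held 0.693%, 14.2% and 45.4% of donor-derived cells. Of endogenous cells it held 5.71%, 53.8% and 50.8%.

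The highest of the other 9 splits gave 5 genes, and 10 splits are again too few for a share under 0.05. Most of the other splits again part the libraries of only 1 time point. Without the time block 175 genes passed, 14 higher and 161 lower, and 12 of the 24 genes chosen by size lost their calls. Counts were 344, 603, 2198, 697 and 802 without the donor-derived library at 90 or 180 dpt or the endogenous one at 28, 90 or 180 dpt. Falls did not outnumber rises in every setting, with 1253 higher and 945 lower without the endogenous library at 28 dpt, 1187 and 905 without the low-count filter, 872 and 768 without shallow clusters and 831 and 732 with the UMI minimum per library. Rises also led with at least 2000 UMIs (764 and 747) and without both 28 dpt libraries (973 and 907). Totals were 835 with DESeq2, 591 with male cells only, and 783 or 81 after background subtraction by the median or summed ratio. All 24 genes chosen by size passed with the block and without each library. As in AT2-like cells, leaving out either library of a time point rests origin on the same other pairs, so these are not separate checks. Background subtraction by the median ratio ended the calls of Chil1 (2.07), Sftpb (1.59), H2-Eb1 (−0.81) and Krt8 (0.34) and turned the sign of Sftpc, Slc34a2, Mgp, Lcn2, Scd1 and Scgb1a1. By the summed ratio, which likely took too much, 33 of 90 named genes lost their calls and 3 turned. Of the genes named here those turned were Sftpc and H2-Eb1, and those lost were Cdkn2c, Igfbp2, Cnn3, Epcam, Krt8, Ctgf, Col4a2, Itgb6, Vegfa, Sema3e, Aqp5, Clu, Sfn, Cdkn1a, Phlda3, Ifit1, Ifit3b, Bex4, Foxp2, Scd1, Scd2, Ldha and Hspa5, at −2.96 (Igfbp2) to 2.73 (Scd1). DESeq2 ended the calls of Slc34a2, Sftpc, Lcn2, Scd1, Ifit1, Ifit3b, H2-Eb1 and Scgb1a1. Male cells only ended the calls of Cdkn1a, Phlda3, Scd1, Aqp5, Ifit1, Krt8 and Scgb1a1, and reporter-positive donor cells those of Ifit1, Krt8 and Ldha. Without the donor-derived or endogenous library at 90 dpt the calls of Itgb6 (−0.44 and −0.38), Sfn (0.34 and 0.38) and Ifit3b (0.52 and 0.57) ended. So did those of Sema3e (−0.37 and −0.31) and Col4a2 (−0.46 and −0.41), which also ended without the endogenous library at 180 dpt (both −0.49). Vegfa lost its call without the donor-derived library at 90 dpt (−0.48) or any endogenous one (−0.47, −0.43 and −0.63), H2-Eb1 without the donor-derived or endogenous one at 28 dpt (−0.46 and −0.41), Scd2 without the donor-derived one at 90 dpt (−0.53) and Scgb1a1 without the endogenous one at 28 dpt (−0.33). Krt8 (0.28 to 0.37), Aqp5 (0.40 to 0.48), Ifit1 (0.45 to 0.51) and Ldha (0.37 to 0.47) lost theirs without the donor-derived library at 90 or 180 dpt or the endogenous one at 180 dpt, and Krt8 also without the endogenous one at 90 dpt. Hspa5 (−0.55 to −0.36) did without the donor-derived library at 90 dpt or any endogenous one.

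Over time in AT2-like cells, the cholesterol synthesis list was called up and the transitional and p53 lists down, though none was with an estimated correlation. Fry called these lists as well. Of 12487 tested genes 526 changed, 293 up and 233 down (slope per doubling of dpt, n = 6 libraries). The largest rises were in Dbp, a clock-output transcription factor gene (2.06 ± 0.39, adjusted p = 0.027), Pon1, paraoxonase (1.02 ± 0.10, adjusted p = 0.0026), Lpl (1.02 ± 0.12) and Nrn1 (0.92 ± 0.17). They were followed by the cystatin gene Cst8 (0.90 ± 0.18), the fatty acid binding protein gene Fabp12 (0.84 ± 0.10), Tgfbi (0.84 ± 0.07) and the guidance gene Ntn1 (0.80 ± 0.15), and by Igfbp6 (0.77 ± 0.10), the chitinase gene Chia1 (0.74 ± 0.15), Adamtsl1 (0.73 ± 0.06) and Tef, another clock-output gene (0.72 ± 0.16). Dbp stepped up only at 180 dpt, at 2.36, 2.88 and 77.3 CPM in donor-derived and 2.28, 2.31 and 105 CPM in endogenous cells. Tef was also late, at 8.15, 7.78 and 31.6 against 10.6, 11.3 and 46.0 CPM. A late step of Dbp was also seen in endogenous fibroblast-like (2.55, 2.59 and 230 CPM) and endothelial-like cells (1.67, 3.67 and 57.9 CPM). Of the falls, the transcriptional repressor gene Zbtb16 fell by 1.25 ± 0.12, Id3 by 1.04 ± 0.07 (adjusted p = 0.0019, chr4:136143497–136145755), Mgp by 0.91 ± 0.16, Sfn by 0.87 ± 0.11 and Kng2 by 0.77 ± 0.15. The TWEAK receptor gene Tnfrsf12a fell by 0.71 ± 0.07, Cdkn1a by 0.71 ± 0.09 (chr17:29090976–29100727), Malt1 by 0.67 ± 0.07, the heat shock gene Hsph1 by 0.66 ± 0.07 and the integrin gene Itga6 by 0.66 ± 0.06. AY036118 (−1.27 ± 0.18) and Lars2 (−0.80 ± 0.12) fell as well, but both can take up reads from ribosomal RNA. Sox9, a tip progenitor regulator, fell by 1.94 ± 0.33 (adjusted p = 0.018) from few counts, 7.70 to 0.136 CPM in donor-derived cells from 28 to 180 dpt. Sftpc (0.03 ± 0.13), Hopx (0.00 ± 0.10), Ager (−0.12 ± 0.08), Nkx2-1 (0.12 ± 0.08) and Krt8 (−0.17 ± 0.06) did not pass.

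In the cholesterol synthesis list 12 of 19 genes rose and 0 fell, with 16 over the list alone (camera adjusted p = 3.44e-18; adjusted p = 0.185 with an estimated correlation). They included Stard4, a sterol carrier gene (0.57 ± 0.08), Msmo1, which encodes a sterol synthesis enzyme (0.41 ± 0.06), and Insig1, a regulator of that pathway (0.40 ± 0.05). In the FGF target list 3 of 14 rose, and 4 over the list alone (adjusted p = 0.00284; adjusted p = 0.342 with an estimated correlation). These were the ETS factor gene Etv5 (0.49 ± 0.07), Spry2 (0.33 ± 0.07) and the receptor gene Fgfr2 (0.33 ± 0.07). MHC class II genes were called up with 1 of 10 rising (0.0176; adjusted p = 0.342 with an estimated correlation), as were airway secretory genes with 1 of 9, Cbr2 (0.65 ± 0.07) (0.0176; adjusted p = 0.342 with an estimated correlation). Transitional genes fell in 8 of 16, and 13 over the list alone, with Anxa1 (−0.56 ± 0.10) and the growth factor gene Areg (−0.33 ± 0.06) next to Sfn and Cdkn1a (5.76e-17; adjusted p = 0.185 with an estimated correlation). TGF-beta, YAP and matrix genes fell in 9 of 22 and rose in 1, with 15 and 2 over the list alone, including Smad7 (−0.44 ± 0.08) and the laminin gene Lama3 (−0.38 ± 0.06) (3.41e-12; adjusted p = 0.185 with an estimated correlation). p53 and senescence genes fell in 5 of 16, and 8 over the list alone, with Gdf15 (−0.57 ± 0.09), Trp53inp1 (−0.45 ± 0.07) and Bax (−0.28 ± 0.06) (7.17e-10; adjusted p = 0.185 with an estimated correlation).

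Further lists were called down with fewer passing genes: stress in 2 of 21, Atf3 (−0.56 ± 0.10) and Hsp90aa1 (−0.39 ± 0.07), and 6 over the list alone (1.09e-08; adjusted p = 0.342 with an estimated correlation). The AT1 programme fell in 5 of 18, among them Col4a3 (−0.60 ± 0.08) and Akap5 (−0.48 ± 0.06) (0.000125; adjusted p = 0.185 with an estimated correlation), and mesenchymal markers in 2 of 10, and 7 over the list alone (1.98e-07; adjusted p = 0.342 with an estimated correlation). Proliferation genes fell in 2 of 20, and over the list alone in 6 with 1 rise (0.00054; adjusted p = 0.367 with an estimated correlation). The unfolded protein response fell in 1 of 17, Ddit3 (−0.33 ± 0.06), and over the list alone in 7 with 1 rise (0.00132; adjusted p = 0.342 with an estimated correlation). Inflammatory genes fell in 1 of 20, Socs3 (−0.46 ± 0.06) (0.00392; adjusted p = 0.185 with an estimated correlation), and interferon genes in 1 of 26 (0.0331; adjusted p = 0.416 with an estimated correlation). Of 16 surfactant genes 0 passed and camera did not call the list, but fry called it up (adjusted p = 0.0291; median slope 0.06). Of 21 fatty acid and phospholipid genes 3 rose, and 5 over the list alone, with Elovl1 (0.44 ± 0.08) and Acly (0.31 ± 0.05), at adjusted p = 0.0735, and fry called this list as well.

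**Figure D4:**
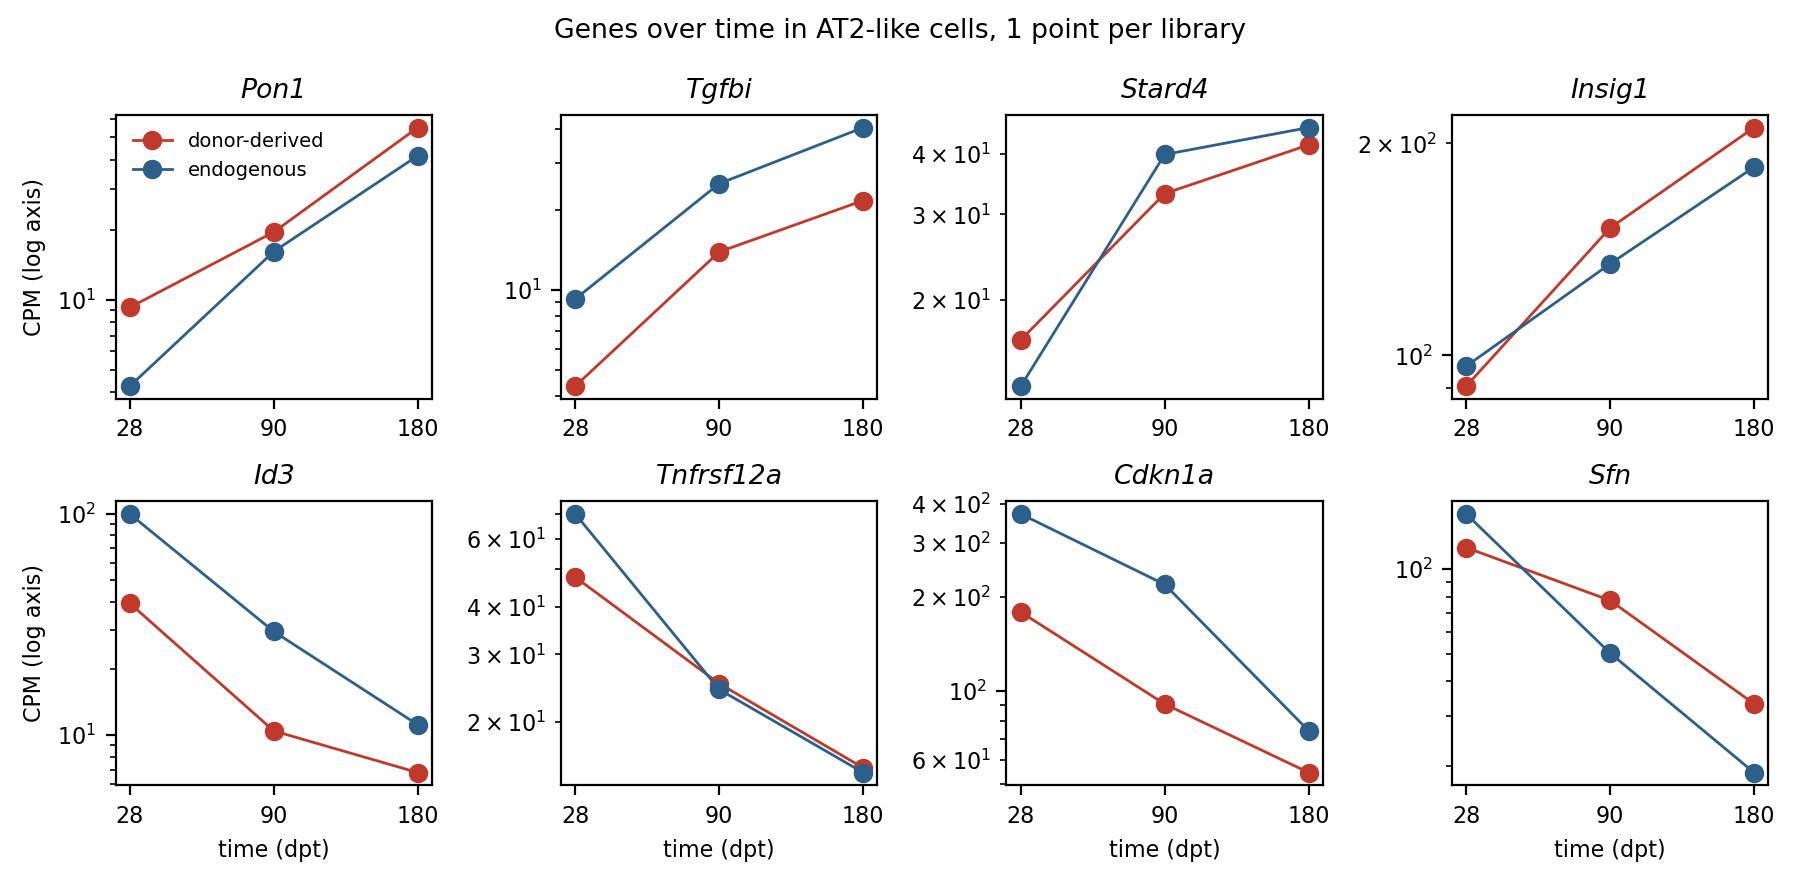
Level of 8 genes in AT2-like cells over time, with 1 point per library. Pon1, Tgfbi, Stard4 and Insig1 rise and Id3, Tnfrsf12a, Cdkn1a and Sfn fall from 28 to 180 dpt.

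The count moved with the libraries used. It was 16 and 69 without the donor-derived and endogenous ones at 28 dpt, 912 and 171 without the donor-derived ones at 90 and 180 dpt, and 302 without the endogenous one at 180 dpt. Without both 28 dpt libraries it was 2208, and 171 of the 293 rises and 88 of the 233 falls were among them. Hsph1, Id3, Lpl, Pon1, Tgfbi and Tnfrsf12a passed without each library. Of the 24 genes chosen by size 16 lost their calls without the donor-derived library at 28 dpt, at slopes from −1.5 (AY036118) to 3.90 (Dbp). Of these Cst8, Igfbp6, Chia1, Kng2, Cdkn1a, Mgp, Ntn1, Tef, Dbp and AY036118 did so without the endogenous one as well, at −1.34 (AY036118) to 2.11 (Dbp), as did Sfn (−0.73) and Malt1 (−0.60). Except for Sfn, Id3, Tgfbi and Lpl, the list members named above lost their calls without the donor-derived library at 28 dpt, at slopes from −0.79 (Cdkn1a) to 0.69 (Cbr2). All but Akap5 and Col4a3 of them did so without the endogenous one too, at −0.74 (Cdkn1a) to 0.61 (Cbr2). Sox9 lost its call without the donor-derived library at 28 (−1.07) or 180 dpt (−1.89). Dbp (1.5), Tef (0.52), Ntn1 (0.67), Lars2 (−0.72), Insig1 (0.37), Msmo1 (0.41) and Etv5 (0.45) lost theirs without the donor-derived library at 180 dpt, and Mgp (−0.82), Tef (0.59), Anxa1 (−0.53) and Hsp90aa1 (−0.39) without the endogenous one. Acly, Elovl1, Areg, Bax, Ddit3, Fgfr2, Lama3 and Spry2 lost theirs without either of these, at −0.42 (Lama3) to 0.42 (Elovl1), and Areg (−0.32) and Bax (−0.28) also without the endogenous library at 90 dpt. Male cells only ended the calls of Areg, Bax and Ddit3, and summed background subtraction those of Akap5 and Lama3. Time may also stand for a processing batch. The 6 libraries share 3 time points, so a shift common to both libraries of a time point is counted in both, and the p values over time do not allow for that.

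Several list calls over time ended when a library was left out. Without the donor-derived library at 28 dpt these were mesenchymal (adjusted p = 0.098), proliferation (0.098), MHC class II (0.285) and airway secretory (0.463). Proliferation (0.0684) and interferon (0.115) ended without that at 90 dpt, and MHC class II (0.0712), airway secretory (0.0629) and interferon (0.0641) without that at 180 dpt. Interferon also ended without the endogenous library at 28 or 180 dpt (0.178 and 0.562). In AT2-like cells without UMIs of other cell types the AT1 programme (0.949), inflammatory (0.694), stress (0.339) and unfolded protein response (0.17) calls ended. That choice left 92, 257 and 184 donor-derived and 20, 7 and 7 endogenous cells at 28, 90 and 180 dpt, and 4046 tested genes. The AT1 marker Ager alone was seen in 91.1% to 96.7% of AT2-like cells. The ended calls cannot be told from the loss of cells, and the choice itself bears on the AT1 programme.

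In AT1-like cells 1997 of 11701 tested genes changed over time, 980 up and 1017 down (slope per doubling of dpt, n = 6 libraries). The AT1 programme list was called up and the stress list down, though neither was with an estimated correlation. Among the rises were Igfbp2 (1.42 ± 0.19, chr1:72824503–72852474), Ankrd1, a YAP target (1.33 ± 0.08, adjusted p = 3e-06, chr19:36111961–36120099), Lrtm2 (1.17 ± 0.10), Lbh (1.07 ± 0.12) and Gpm6a (1.06 ± 0.12). So were the LIM protein gene Pdlim3 (1.00 ± 0.10), the cilium gene Cys1 (1.08 ± 0.17), the ligand gene Wnt10b (0.96 ± 0.12) and Igfbp6 (0.94 ± 0.17), with Dbp again largest (2.36 ± 0.43, adjusted p = 0.003). Its step again came only at 180 dpt, at 1.80, 1.15 and 103 CPM in donor-derived and 2.61, 2.40 and 58.7 CPM in endogenous cells. Rnaset2b (1.09 ± 0.15) and Rnaset2a (1.05 ± 0.20) are near-identical copies whose counts cannot be told apart with certainty. Zbtb16 fell by 2.12 ± 0.16 and Mgp by 1.55 ± 0.08. The immediate early genes Fosb fell by 1.34 ± 0.16, Atf3 by 1.06 ± 0.13 and Egr1 by 1.06 ± 0.14. The heat shock gene Hspa1a fell by 1.07 ± 0.13, Scd1 by 1.05 ± 0.15 and Fn1 by 1.03 ± 0.13. AY036118 fell by 1.23 ± 0.11, with the doubt about ribosomal reads given above. Igha (−4.06 ± 0.26), Jchain (−2.81 ± 0.35) and Igkc (−1.89 ± 0.40) fell as well, with most of their UMIs in 1 endogenous cell per gene at 28 dpt. Without that library Igha still passed at −1.90, from 24, 2 and 0 donor-derived UMIs at 28, 90 and 180 dpt. Hopx rose (0.36 ± 0.09, adjusted p = 0.013), and Ager (0.17 ± 0.10), Sftpc (−0.16 ± 0.12), Nkx2-1 (0.10 ± 0.07) and Epcam (−0.11 ± 0.07) did not pass.

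The AT1 programme was the only list called up, with 9 of 18 genes rising, and 10 rising and 1 falling over the list alone, among them Vegfa (0.59 ± 0.08) and Gprc5a (0.33 ± 0.07) (camera adjusted p = 0.00101; adjusted p = 0.351 with an estimated correlation). Stress genes fell in 16 of 21 and rose in 1, with 18 and 1 over the list alone (1.41e-20; adjusted p = 0.317 with an estimated correlation). Ier2 (−0.94 ± 0.09), Zfp36 (−0.59 ± 0.07) and Junb (−0.57 ± 0.06) fell and Ier3 rose (0.79 ± 0.08). p53 and senescence genes fell in 7 of 16 and rose in 1, with 9 and 1 over the list alone (0.000138; adjusted p = 0.317 with an estimated correlation). Cdkn1a (−0.65 ± 0.06) and Trp53inp1 (−0.66 ± 0.06) fell and Perp (0.66 ± 0.10) rose. MHC class II genes fell in 4 of 7, and 5 over the list alone, with H2-Ab1 (−0.78 ± 0.12) and its chaperone gene Cd74 (−0.45 ± 0.09) (0.000299; adjusted p = 0.355 with an estimated correlation). Surfactant genes fell in 5 of 16, among them Napsa (−0.43 ± 0.10) (0.00481; adjusted p = 0.403 with an estimated correlation). The unfolded protein response fell in 3 of 16 and rose in 1, with 8 and 1 over the list alone, including Manf (−0.29 ± 0.06) (0.0108; adjusted p = 0.322 with an estimated correlation). Tip progenitor and fetal genes fell in 3 of 6, with Bex4 (−0.94 ± 0.07) (0.0272; adjusted p = 0.429 with an estimated correlation). Mesenchymal markers fell in 9 of 12 (8.84e-09; adjusted p = 0.317 with an estimated correlation). Camera did not call the following lists. In TGF-beta, YAP and matrix 6 of 20 rose and 4 fell, or 6 and 5 over the list alone, with Tgfb2 (0.33 ± 0.06) up and the BMP target Id1 (−0.65 ± 0.06) down. In glycolysis and hypoxia 4 of 16 rose and 1 fell, with Gapdh (0.40 ± 0.08) and Pfkp (0.32 ± 0.06) up and adjusted p = 0.0522, while fry called it up (0.0402). FGF targets rose in 4 of 11, among them Bmp4 (0.61 ± 0.12) and Fgfrl1 (0.41 ± 0.07).

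**Figure D5:**
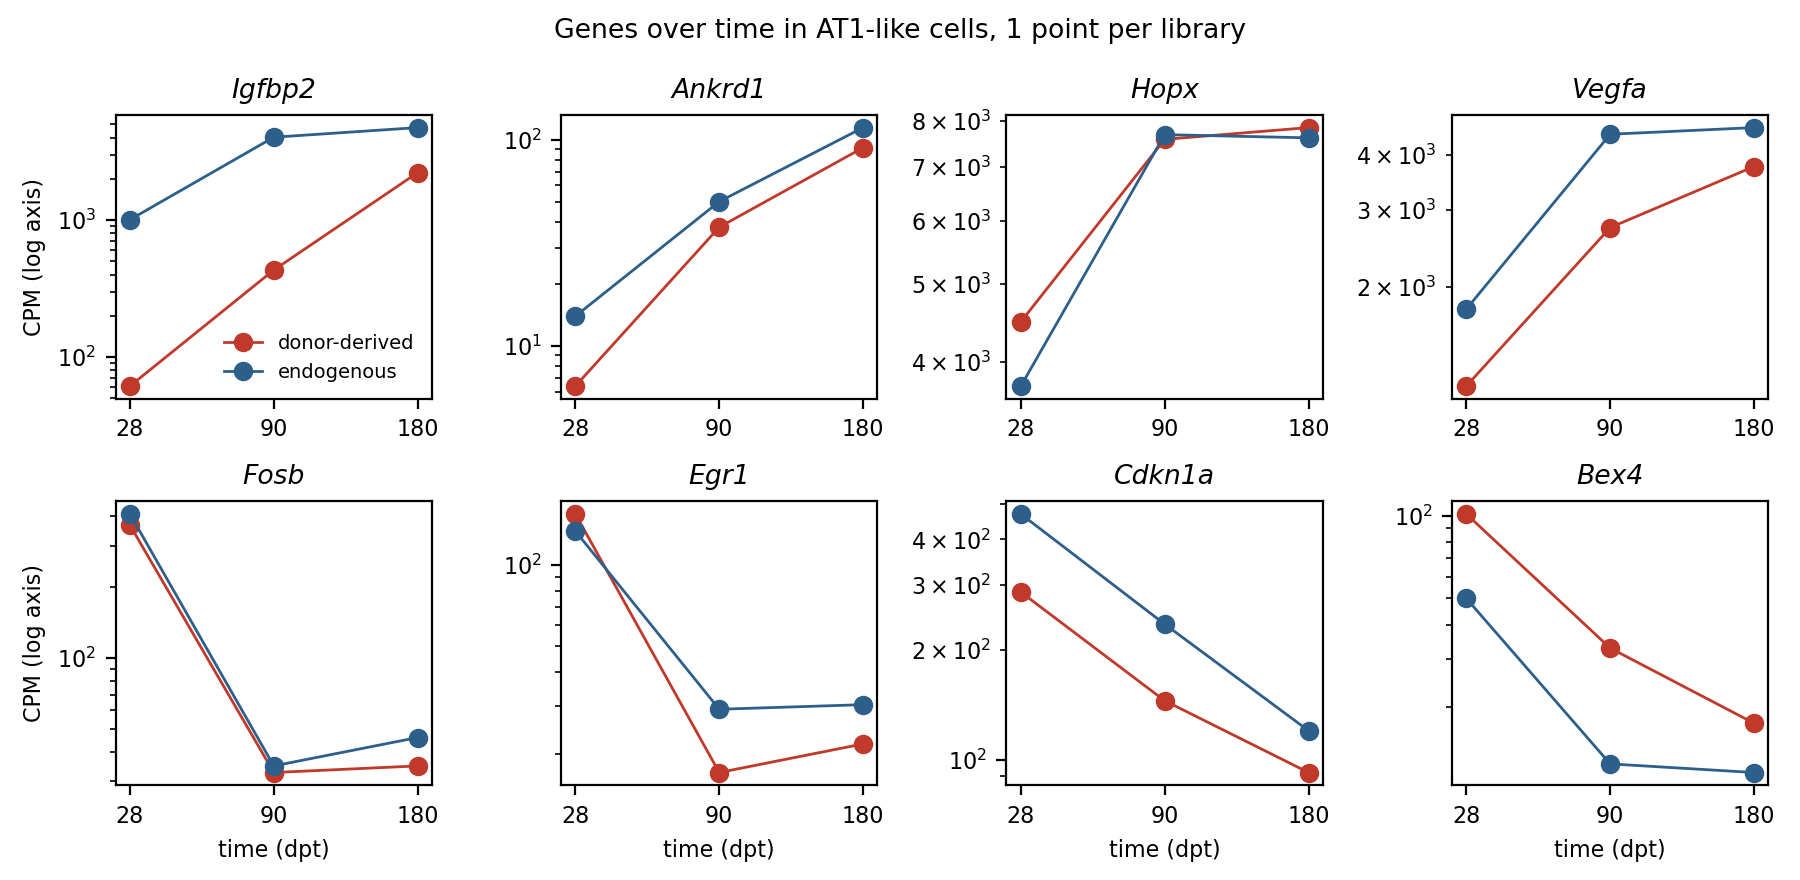
Level of 8 genes in AT1-like cells over time, with 1 point per library. Igfbp2, Ankrd1, Hopx and Vegfa rise and Fosb, Egr1, Cdkn1a and Bex4 fall from 28 to 180 dpt.

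Counts were 292 and 714 without the donor-derived and endogenous libraries at 28 dpt and 703 without the donor-derived one at 180 dpt. The cluster changes given above for AT1-like cells run along the same time axis. As in AT2-like cells, the p values treat the 2 libraries of a time point as separate. Summed background subtraction, with the same excess at 28 dpt, ended the calls of 31 of 101 named genes and turned 1. Of the genes named here it ended those of Egr1 (−0.79), Scd1 (−0.35), Hopx (0.27), Gprc5a (0.25), Ier2 (−0.70), Zfp36 (−0.17), Junb (−0.29) and H2-Ab1 (−0.44), and the median ratio ended that of Scd1 (−0.76). Male cells only ended 11 calls of the named genes, none of them given here. Of the 24 genes chosen by size 17 passed without each library. Without the donor-derived library at 28 dpt Cys1 (0.65), Egr1 (−0.71), Igfbp6 (0.59), Rnaset2b (0.79) and Rnaset2a (0.69) lost their calls, as did Perp (0.44), Pfkp (0.32), Hopx (0.36), Gprc5a (0.37), Bmp4 (0.47), Gapdh (0.39) and Manf (−0.31) among list members. Without the endogenous one at 28 dpt Rnaset2a (0.91), Igkc (−0.48), Jchain (−0.94), Hopx (0.28), Gprc5a (0.32), Bmp4 (0.53), Gapdh (0.32), Manf (−0.25), Cd74 (−0.29), Napsa (−0.19) and Tgfb2 (0.29) did, and Gprc5a (0.27) also without the donor-derived one at 180 dpt. Of the list calls, mesenchymal ended without the donor-derived library at 28, 90 or 180 dpt (adjusted p = 0.239, 0.206 and 0.0653) and tip progenitor and fetal without that at 28 dpt (0.0645). MHC class II (0.0581) and surfactant (0.298) ended without the endogenous one at 28 dpt, and the unfolded protein response without the endogenous one at 28 or 180 dpt (0.0657 and 0.18).

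Whether the change over time differed by origin in AT2-like cells was tested directly. With edgeR 0 of 12487 genes passed, 355 had an unadjusted p under 0.05, and DESeq2 called 16, with 180 at an unadjusted p under 0.05. The 5 genes with the smallest p for a steeper rise in donor-derived cells were the chemokine gene Ccl3 (7.40 ± 0.77), Fxyd3 (1.74 ± 0.21), Tmem252 (1.39 ± 0.18), Cyp2f2 (0.99 ± 0.13) and Dmkn (0.93 ± 0.12), each at adjusted p = 0.22. In the other direction they were the immunoglobulin gene Ighm (−1.22 ± 0.17, adjusted p = 0.3), Slc38a1 (−1.52 ± 0.29, 0.69), Vsig2 (−0.70 ± 0.14, 0.78), Igkc (−1.08 ± 0.22, 0.91) and Sdc3 (−1.96 ± 0.41, 0.92). These genes were chosen by p and not by level. A difference as large as that of Ccl3 may rest on few or no counts in some libraries, so its size should not be read as a fold change. Leaving out 1 library gave 11, 20 and 32 genes without the donor-derived and 8, 41 and 1 without the endogenous library at 28, 90 and 180 dpt. On simulated data the test found 24.2% of 4-fold differences, so differences of this kind stay open.

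No other epithelial class had 20 cells in every library. Club and secretory-like cells numbered 16 in the endogenous library at 180 dpt and ciliated-like cells 10 in the donor-derived library at 28 dpt, so origin was not tested in them.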

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

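Of the tests in this part, the comparison of AT2 markers without Napsa and that of the excess of Napsa were chosen after the data were seen.

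The tdTomato transcript appeared in cells that the comparisons above do not use. It was seen in 2.51%, 0.634% and 0.777% of the non-epithelial cells of the donor-derived libraries at 28, 90 and 180 dpt (11 of 438, 5 of 789 and 6 of 772 cells). In their ciliated-like cells it was seen in 1.49% (1 of 67; interval 0.0378 to 8.04) at 90 dpt and 5% (2 of 40; 0.611 to 16.9) at 180 dpt, and in 0 of 10 at 28 dpt, with an exact upper limit of 30.8%. They were flagged because the called cells of the endogenous libraries had 0 reporter UMIs. Those libraries are no control for free reporter RNA, which stood at 52.0, 39.0 and 23.3 CPM in the donor-derived and 1.75, 0.350 and 0.728 CPM in the endogenous background. The donor-derived non-epithelial cells held 5.24, 1.48 and 2.20 CPM, which free RNA may give, and this was not tested. The share of free RNA was not estimated in them. In AT2-like and AT1-like cells of these libraries it was 0.769% to 5.27% by the median ratio. Of the non-epithelial cells 48.6%, 51.3% and 53.9% held Y-linked UMIs and no Xist. Only 1.83%, 0.380% and 1.17% held Xist and no Y-linked UMI. In club and secretory-like cells the donor-derived shares were 47.6%, 32.1% and 25.9%.

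Of 10 splits of the libraries into 3 and 3, 1 gave at least as many genes as the split by origin in AT2-like cells, and 1 did in AT1-like cells, in each case the real one, with 1243 and 1309 genes against at most 0 and 5. With 10 splits no share under 0.05 can be reached, and most of the others part the libraries of only 1 time point. A chance arrangement of the libraries is therefore not excluded by this count.

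The clock index rose late in cells of both origins. The index, the mean log2 CPM of Dbp, Tef, Nr1d1, Nr1d2, Per3 and Ciart minus that of Arntl, Npas2, Clock and Nfil3, rose from 28 to 180 dpt by 3.45 in endogenous AT1-like and 4.26 in AT2-like cells, and did not rise by 90 dpt (−0.63 and −0.64). In other endogenous classes it also rose, by 3.49 in endothelial-like, 6.15 in fibroblast-like, 1.22 in macrophage-like, 0.777 in T and NK-like and 0.773 in B and plasma-like cells. The median of these 5 was 0.353 of the AT1-like rise, between the bounds of 1/2 for and 1/4 against a shift of the whole library, such as the hour of collection. That shift and a biological change with time therefore cannot be told apart, and both may contribute. In the donor-derived libraries, which the bounds did not use, the index rose by 4.43 in AT1-like and 4.26 in AT2-like cells. By 90 dpt it had moved there by −0.583 and −0.36. From few cells, it rose by 3.24 in donor-derived endothelial-like, 7.41 in fibroblast-like, 1.83 in macrophage-like, 1.29 in T and NK-like and 1.18 in B and plasma-like cells.

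Genes called over time in AT1-like cells could reflect handling or a batch that acts on whole libraries. In endogenous non-epithelial classes a median of 63.9% of them moved the same way from 28 to 180 dpt (endothelial-like 68.5%, fibroblast-like 70.1%, T and NK-like 63.9%, macrophage-like 60.2%, B and plasma-like 51.6%), against 49.4% to 57.6% of the genes not called. This lies between the bounds of 70% for and 60% against such a shift and leaves it open. By direction it was a median of 78.8% of the rises (74.6% to 89.0%) and 50.8% of the falls (34.8% to 60.5%). Genes not called showed a like split, with medians of 69.3% and 34.6%, as a median of 69.6% of them rose in these classes. The bounds did not allow for that drift, so neither part decides. Dissociation stress was not decided either. Stress list and heat shock genes were 1.40% of the calls (28 genes), but with 79 of them tested they could not have passed 3.86%, so the share was low by design. A biological change with age or time after transplantation also stays open, as untested.

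AT2 markers were higher in donor-derived AT1-like cells, and free RNA or doublets might carry them there. The background share that 8 called markers would need was 0.564, 1.45 and 2.18 times the share estimated from other genes at 28, 90 and 180 dpt, so free RNA fits 2 libraries, exceeds the bound of 2 in the third, and stays open. In endogenous AT1-like cells the same ratio was 2.09, 1.49 and 0.758, so a value over 2 was not particular to donor-derived cells. For doublets the bound against them was a ratio over 10 between markers, and Napsa, at 10.5% of its AT2-like level while the others stood at 0.798% to 1.26%, gave 13.1. That bound was wrong, since it counts what AT1-like cells of either origin make: in endogenous AT1-like cells Napsa stood at 12.2%, 4.74% and 3.62% of its AT2-like level. As an excess over endogenous cells, Napsa was 0.774%, 7.17% and 4.25% of its AT2-like level, which lay within the range of the others at 28 dpt and above their highest values, 1.26% and 0.811%, at 90 and 180 dpt. The gap was 3.04 ± 1.79 points (SE over 3 time points), within its spread, so doublets stay open too. Without Napsa the ratio over 7 markers was 1.58, which is what free RNA or doublets with 1 fixed mix would give, though a low AT2-like programme in these cells would give it as well. The 2 origins also differ in how many AT2-like cells they hold, so a difference between donor-derived and endogenous cells stays open and untested.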

How the results depend on the processing

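Male cells only, reporter-positive donor cells, clusters of low depth left out, background subtraction, the interaction without each library and the list tests in AT1-like cells were chosen after the data were seen, and the other alternatives before. Where a count moved without fewer cells, genes or libraries, the cause was not tested.

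The difference in epithelial share (86.1 points) moved to 80.8 at Leiden resolution 2 and 84.6 with doublet calls kept. The difference in the AT1-like share of AT1-like and AT2-like cells (7.49 points) fell to 2.70 points with doublet calls kept. The total of called cells stayed within 1.5 times under all 4 other cell filters, though the endogenous library at 90 dpt went from 11422 to 7436 cells under the UMI minimum per library. For origin in AT2-like cells (1243 genes) the count was 2261 without the low-count filter, 531 with equal cell numbers, 815 with male cells only, 437 and 507 after background subtraction by the median and summed ratio, 582 without the replicate block of time points, 2100 and 704 without both 28 or both 90 dpt libraries, and 13 in cells without UMIs of other types (92, 257 and 184 against 20, 7 and 7 cells). Leaving out 1 library gave 727 to 2285.

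For origin in AT1-like cells (1309) it was 835 with DESeq2, 2092 without the low-count filter, 2134 with doublet calls kept, 255 with equal cell numbers, 591 with male cells only, 619 with reporter-positive donor cells, 783 and 81 after background subtraction by the median and summed ratio, 175 without the replicate block, and 664 and 823 without both 90 or both 180 dpt libraries. The summed ratio rose to 30.1% with the plasma cell genes of the endogenous library at 28 dpt and was 4.15% without them, so its values in AT1-like cells may overstate the loss. Leaving out 1 library gave 344 to 2198. For time in AT2-like cells (526) it was 890 with DESeq2, 1567 without the low-count filter, 13 in cells without UMIs of other types, 2180 with time as a factor and 2208 without the 28 dpt libraries, and 16 to 912 without 1 library. For time in AT1-like cells (1997) it was 753 with equal cell numbers, 1113 with male cells only, 1315 with reporter-positive donor cells, 929 after summed background subtraction, 3128 with time as a factor and 1019 without the 28 dpt libraries, and 292 to 2276 without 1 library. The origin by time difference (0) gave 16 with DESeq2, 101 without the low-count filter and 1 to 41 without 1 library. All other settings kept each count within 1.5 times.

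Of the lists, 10 were called by origin in AT2-like cells, and 0 with an estimated correlation or with fry. In AT1-like cells 7 were called by origin, 0 with an estimated correlation, 3 with fry and 7 to 11 without 1 library. Over time 14 were called in AT2-like cells, 0 with an estimated correlation, 8 with fry and 8 in cells without UMIs of other types, and 8 in AT1-like cells, 0 with an estimated correlation, 3 with fry and 6 to 13 without 1 library. The 8 in cells without UMIs of other types rest on 7 cells in some libraries. With an estimated correlation, the lowest adjusted p per comparison was 0.185 to 0.317, also where nearly all genes of a list passed. As that form was not tried on simulated lists, its lack of calls does not count against a list.

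Single genes turned as follows. With male cells only, Ddx3y went to 0.19 and Eif2s3y to 0.24 by origin in AT1-like cells. In AT2-like cells they went to 0.10 and 0.12, and Tsix went to −0.74. This setting was meant to hold sex constant. Whether the male cells of the donor-derived libraries were all donor-derived was not tested, so it may change origin as well. The choice of these cells by Y-linked UMIs and no Xist sets the values of Ddx3y and Eif2s3y. It also bears on Tsix, which overlaps Xist. Background subtraction by the median ratio turned Lcn2 (−1.34), Mgp (9.41), Scd1 (−0.0149), Scgb1a1 (0.63), Sftpc (−1.13) and Slc34a2 (−0.74) by origin in AT1-like cells, Fmo2 (0.18) by origin in AT2-like cells, and Lcn2 (0.18) and Slc34a2 (0.51) over time in AT1-like cells. By the summed ratio it turned H2-Eb1 (1.04), Klf4 (0.70) and Sftpc (−3.60) by origin and Sftpc (5.36) over time in AT1-like cells. In AT2-like cells Bex4, not called with all libraries, went to −0.49 and −0.51 by origin without the endogenous and donor-derived libraries at 28 dpt. For the named genes, direction and side of the threshold held in 1561 of the values by origin in AT2-like cells (70 newly passed, 126 no longer passed, 6 turned), and in AT1-like cells in 1145 (54, 211 and 11). Over time they held in 1507 in AT2-like cells (29, 125 and 0) and in 1194 in AT1-like cells (10, 177 and 3), and for the origin by time difference in 264 (37, 0 and 0).

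Cell numbers limit the endogenous epithelium: its AT2-like counts came from 270, 244 and 245 cells and its AT1-like counts from 368, 240 and 187 cells. No alternative chosen before the data were seen was left out, except that other epithelial classes had too few cells for any test.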

Other observations

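No explanation is tested in this part, and its values were chosen after the data were seen.

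A small AT1-like cluster of 183 cells was led by the interferon-induced genes Ifit3, Ifit1 and Isg15. It held 67 of 4327, 77 of 5421 and 32 of 4258 donor-derived AT1-like cells at 28, 90 and 180 dpt, or 1.55% (1.20 to 1.96), 1.42% (1.12 to 1.77) and 0.752% (0.515 to 1.06). Of the endogenous ones it held 5 of 368, 2 of 240 and 0 of 187. A cluster of 50 AT2-like cells was led by Lyz1, a lysozyme gene, and the chitinase gene Chia1. It held 0 of 2310, 3 of 4948 and 0 of 3408 donor-derived and 9 of 270, 21 of 244 and 17 of 245 endogenous AT2-like cells, which is 3.33% (1.54 to 6.23), 8.61% (5.41 to 12.9) and 6.94% (4.09 to 10.9) of the endogenous ones. Intervals are exact and cover counting error only.

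Sex-linked transcripts in the ciliated-like cells of the donor-derived libraries were mostly male. Of these cells 6 of 10, 42 of 67 and 27 of 40 held Y-linked UMIs and no Xist at 28, 90 and 180 dpt, and 0, 3 and 2 held Xist alone, at median depths of 12608, 9464 and 10322.5 UMIs. In the endogenous library at 28 dpt, Xist reached 40.0 CPM in AT2-like and 31.3 CPM in AT1-like cells, where 5 of 270 and 12 of 368 cells held Xist and no Y-linked UMI.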
